A study of Homo sapiens with 10 samples.

How the data were processed

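According to the labels, the 10 arrays were two-colour hybridisations of amplified total RNA, and each compared a treated culture with a mock-treated one. The 6 TERA2 arrays came as scanner files, written by Agilent Feature Extraction 8.1.1.1 per the file headers, on 6 slides, 1 scanner and 1 scan day. Per the file headers, the deposited TERA2 files hold intensity values for the median signal and background of each channel, and log10 values for the software's own log ratios. The 4 HCT116 arrays came only as columns of the authors' value table, whose unit is log2 of treated over mock per the labels. The submitters' processing notes credit limma (no version given) for background subtraction, loess and scaling to the same interquartile range, with averaging over dye-swapped replicates. The genome build was not given in the sources used here, and the RefSeq table was used for names alone.

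Direction was checked on the TERA2 columns of the value table, which correlated across probes with the scanner values computed here at r = 0.994 to 0.997 and were positive where the treated channel was brighter. Per the labels, TERA2 replicate 1 had the treated RNA in Cy5 and replicate 2 in Cy3, so the sign of replicate 2 was turned. HCT116 arrays all had the treated RNA in Cy5, and nothing was turned. The series design speaks of dye-swapped replicates, which the HCT116 labels do not show.

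Each TERA2 array had 43931 spots, of which 2256 were controls. Its 41000 probes were given 31388 gene labels: 22445 probes took a name through their accession and 18555 kept the name in the files. There were 16643 labels with a gene symbol, and 7324 genes had several probes, of which the probe with the highest mean intensity was used. Median signals were corrected by the normexp method with an offset of 50 and normalised by loess within each array. A gene was kept where it was well above background in either channel on at least 2 of the 6 arrays, which left 29851 genes. The share of spots well above background was 89.3% to 92.4% in red and 84.8% to 90.6% in green, and 20 to 129 red and 1 to 14 green spots were saturated. Between 9 and 47 spots per array carried a quality mark of the scanner software and were left out of the normalisation and of the probe values. For HCT116 no spot background was available, so all 31388 genes were tested.

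The tools were R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). Genes were tested with limma (lmFit and eBayes, Benjamini-Hochberg adjustment over all genes of a comparison, threshold 0.05). All 6 TERA2 arrays shared a spread in 1 fit, as did the 4 HCT116 arrays; differences between the lines were contrasts over the 10 columns of the value table. There were 22 gene lists, of pluripotency, retinoid target, HOX, neural, endoderm and trophoblast, mesenchyme and matrix, colon epithelium, imprinted, cancer-testis, tumour-hypermethylated, p53 target, interferon response, HLA and antigen presentation (class I and class II), G1/S, G2/M, replication-dependent histone, metallothionein, deacetylase inhibitor-induced, Polycomb and DNA methylation, deacetylase and acetyltransferase, ribosomal protein and endogenous reference genes. They were written down, as was the rule for choosing named genes, before the data were examined. Lists were tested with limma camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with limma fry. With the estimated correlation, camera has only the residual degrees of freedom: 3 in TERA2, 2 in HCT116 and 5 between the lines. A call that ended there may reflect the few arrays and does not show that the members vary together. Lists with at least 5 measured genes were tested, and the p-values were adjusted over the lists of a comparison.

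Genes named in the text were chosen by rule. Per treatment, these were the 8 highest and 8 lowest genes past the threshold with the same sign on both arrays, up to 4 members of each list with the largest change past the threshold, and 12 genes followed in every comparison. For differences between treatments or lines, the 4 highest and 4 lowest past the threshold were taken. Genes known by an accession or clone alone were left out of the highest and lowest. A few genes that the rule chose, 1 of the 12 followed genes among them, are not reported here.

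Replicate numbers are the same thing as the dye orientation on the TERA2 arrays. Arrays of different treatments with the same number were more alike (ATRA and Aza, r = 0.650 for replicate 1) than arrays with different numbers (r = 0.552), so a fit with the replicate number as a block was run beside each test. Replicates of a group correlated at 0.883 for ATRA, 0.842 for Aza and 0.820 for TSA in TERA2, and in the value table at 0.876 for 5Aza and 0.768 for TSA in HCT116. Alternatives tried were plain background subtraction, scaling of all arrays to the same interquartile range, the scanner software's own ratios, no filter or a stricter filter on dim probes, the mean of a gene's probes, the replicate block, other sets of arrays in the fit, the authors' value table for TERA2, and each array left out in turn. Covariances between treatments were set beside simulated unchanged groups with a shared mock.

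In a self-test, the same code was run on simulated arrays with the measured spread and 200 changed genes. It recovered 23.9% of 1.5-fold, 61.2% of 2-fold and 93.9% of 4-fold changes for ATRA in TERA2, and 26.9%, 79.1% and 92.4% for Aza. For 5Aza in HCT116 it recovered 0%, 38.8% and 66.7%, and for TSA 0%, 28.4% and 80.3%. Between 5Aza and TSA in HCT116 it found 22.7% of the 4-fold changes. Far more genes passed in the data (11651 after 5Aza in HCT116, down to log2 0.28). The adjustment was less strict there, so these shares do not apply. The number of arrays limits the precision of each result. Genes of the sex chromosomes that mark the sex of a donor were left out.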

Results

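The series measured RNA on two-colour Agilent arrays, each of which compared a treated culture with a mock-treated culture of the same human cell line. TERA2 is an embryonal carcinoma line, a tumour cell type that expresses pluripotency genes, and HCT116 is a colon carcinoma line. There were 5 groups of 2 arrays each. TERA2 cells received all-trans retinoic acid (ATRA, a ligand of retinoic acid receptors; 2 µM, 12 days), an azacytidine drug (an inhibitor of DNA methyltransferases; 5 µM, 72 h) or trichostatin A (TSA, an inhibitor of histone deacetylases; 300 nM, 18 h). HCT116 cells received the azacytidine drug at 5 µM for 96 h or TSA at 300 nM for 18 h. The labels write the azacytidine drug as Aza for TERA2 and 5Aza for HCT116 and do not say which analog it was, so the lines may have received different analogs. The TERA2 arrays were taken from the scanner files and covered 29851 genes well above background, and the HCT116 arrays came from the authors' value table with 31388 genes. Median signals on the TERA2 arrays were 174 to 255 in red over a background of 59 to 61, and 133 to 196 in green over a background of 48 to 50. Values below are log2 of treated over mock as mean ± SD of n = 2 arrays, with p-values from limma adjusted over all genes of a comparison. Those p-values measure the spread between arrays, which may be technical, since the labels do not say whether the arrays came from separate cultures.

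How did 12 days of retinoic acid change TERA2 cells? Cell cycle genes fell, and extracellular matrix and retinoid target genes rose. Pluripotency genes fell and p53 targets rose too, but with an estimated correlation those list calls ended undecided. The retinoic acid-degrading enzyme gene CYP26B1 rose 52.3-fold (log2 5.71 ± 0.04, n = 2, adjusted p = 2.6e-05, 1 other probe 1.62). UBD, a ubiquitin-like modifier, rose 23.8-fold (log2 4.58 ± 0.02, n = 2, adjusted p = 6e-06). The de novo DNA methyltransferase DNMT3B fell 44.9-fold (log2 -5.49 ± 0.42, n = 2, adjusted p = 6.94e-06), and the pluripotency factor NANOG fell 35.1-fold (log2 -5.14 ± 0.11, adjusted p = 6e-06). POU5F1, which encodes the pluripotency factor OCT4, fell at least 23.0-fold, a lower bound because its mock signal was saturated on both arrays (log2 -4.53 ± 0.33, adjusted p = 1.79e-05, 3 other probes -4.93 to -4.51).

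Other genes among the largest rises after ATRA were ANGPTL4, an inhibitor of lipoprotein lipase (log2 4.45 ± 0.22), the vitamin D receptor VDR (log2 4.32 ± 0.07), and IGFBP6, which binds insulin-like growth factors (log2 4.19 ± 0.03). Adenosine deaminase ADA (log2 4.08 ± 0.15), the natriuretic peptide precursor NPPB (log2 3.91 ± 0.36) and the cytokine GDF15 (log2 3.78 ± 0.18) rose as well. The largest falls included CRIPTO, a co-receptor of Nodal (log2 -4.59 ± 0.06, 1 other probe -2.02), the cathepsin CTSV (log2 -4.38 ± 0.04), and FGFR3, a fibroblast growth factor receptor (log2 -4.23 ± 0.12, 1 other probe -0.54). L1TD1, an RNA-binding protein of pluripotent cells (log2 -4.10 ± 0.22), and the recombination factor RAD51AP1 (log2 -3.94 ± 0.15) fell too. Among the 11 genes followed in every comparison, the protease inhibitor TIMP3 rose (log2 2.09 ± 0.05, 1 other probe 0.17), as did the cell cycle inhibitors CDKN2A (log2 1.99 ± 0.03) and CDKN1A (log2 1.69 ± 0.05). The retinoid-metabolizing CYP26A1 (log2 1.77 ± 0.01) and the endoderm factor GATA4 (log2 0.72 ± 0.17, 1 other probe 0.12) also rose. EZH2, the methyltransferase of Polycomb complex 2 (log2 -1.77 ± 0.03, 1 other probe -0.19), and the Wnt antagonist SFRP1 (log2 -0.69 ± 0.07) fell. SOX17 (log2 0.14) did not pass.

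In the pluripotency list, 24 of 36 fell, 0 rose and 12 did not pass (25 and 0 adjusted over the list alone). Pluripotency genes had a median of log2 -1.23 (adjusted p = 9.24e-15, and adjusted p = 0.112 with an estimated correlation), and DNMT3B, NANOG, CRIPTO and POU5F1 were the largest falls. G2/M cell cycle genes fell as a group: 34 of 34 fell, 0 rose and 0 did not pass (34 and 0 adjusted over the list alone). G2/M genes had a median of log2 -2.60 (adjusted p = 2.79e-33, and adjusted p = 0.0428 with an estimated correlation), among them BIRC5 (log2 -3.75) and CDK1 (log2 -3.71). Among genes of G1/S and DNA replication, 31 of 33 fell, 0 rose and 2 did not pass (32 and 0 adjusted over the list alone). G1/S genes had a median of log2 -1.82 (adjusted p = 4.48e-27, and adjusted p = 0.0428 with an estimated correlation), including RRM2 (log2 -3.40) and TK1 (log2 -3.30). Among replication-dependent histone genes, near-identical paralogs whose probes are uncertain, 24 of 28 fell, 0 rose and 4 did not pass (24 and 0 adjusted over the list alone). Histone genes had a median of log2 -0.97 (adjusted p = 6.92e-16, and adjusted p = 0.0428 with an estimated correlation), for example H3C10 (log2 -3.29). Mesenchyme and matrix genes rose: 24 of 39 rose, 1 fell and 14 did not pass (26 and 2 adjusted over the list alone). Mesenchyme genes had a median of log2 1.05 (adjusted p = 1.22e-11, and adjusted p = 0.0428 with an estimated correlation), with IGFBP3 at log2 3.73 and fibronectin FN1 at log2 2.91. For retinoid targets, 16 of 27 rose, 1 fell and 10 did not pass (17 and 2 adjusted over the list alone). Retinoid targets had a median of log2 0.78 (adjusted p = 4.13e-07, and adjusted p = 0.0428 with an estimated correlation), among them the orphan receptor NR2F1 (log2 2.41) and the retinal reductase DHRS3 (log2 2.23). Of p53 targets, 24 of 35 rose, 3 fell and 8 did not pass (24 and 3 adjusted over the list alone). These p53 targets had a median of log2 0.61 (adjusted p = 2.79e-08, and adjusted p = 0.0805 with an estimated correlation), for example PLK2 (log2 3.10) and TP53INP1 (log2 1.83).

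After ATRA, 6 further lists shifted. HLA and antigen presentation genes, of class I and class II, rose: 12 of 18 rose, 0 fell and 6 did not pass (12 and 0 adjusted over the list alone). HLA and presentation genes had a median of log2 0.85 (adjusted p = 4.66e-06, and adjusted p = 0.0513 with an estimated correlation), including the peptide transporter TAP1 (log2 2.06) and HLA-B (log2 1.54; HLA paralogs are uncertain). Of the HOX genes, 12 of 36 rose, 0 fell and 24 did not pass (13 and 0 adjusted over the list alone). HOX genes had a median of log2 0.08 (adjusted p = 0.00153, and adjusted p = 0.124 with an estimated correlation), with HOXB2 at log2 2.30 and HOXA5 at log2 1.74. Among imprinted genes, 13 of 36 rose, 5 fell and 18 did not pass (14 and 5 adjusted over the list alone). Imprinted genes had a median of log2 0.14 (adjusted p = 0.0276, and adjusted p = 0.133 with an estimated correlation). H19 rose (log2 2.95) and CDKN1C fell (log2 -2.21). Among interferon response genes, 13 of 47 rose, 3 fell and 31 did not pass (15 and 3 adjusted over the list alone). Interferon response genes had a median of log2 0.18 (adjusted p = 0.00740, and adjusted p = 0.202 with an estimated correlation). IFI16, a DNA sensor, rose (log2 2.41) and IFITM1 fell (log2 -1.75). Among genes often hypermethylated in tumours, 25 of 75 rose, 12 fell and 38 did not pass (28 and 12 adjusted over the list alone). Tumour-hypermethylated genes had a median of log2 0.12 (adjusted p = 0.00878, and adjusted p = 0.0998 with an estimated correlation). The matrix protein EFEMP1 (log2 3.64) and the cell cycle inhibitor CDKN2B (log2 3.34) rose, and E-cadherin CDH1 fell (log2 -2.43). This list's call ended when members shared with other lists were left out (adjusted p = 0.102). Among Polycomb and DNA methylation genes, 15 of 37 fell, 5 rose and 17 did not pass (15 and 6 adjusted over the list alone). Polycomb genes had a median of log2 -0.08 (adjusted p = 0.0339, and adjusted p = 0.253 with an estimated correlation). UHRF1, needed for maintenance methylation, fell (log2 -2.34) and PHC2 rose (log2 2.12). That call ended with a replicate block (adjusted p = 0.0687), without shared members (adjusted p = 0.251) and without TERA2_ATRA replicate 1 (adjusted p = 0.0517).

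In the test, 8132 of 29851 genes passed at an adjusted p under 0.05, 4248 higher and 3884 lower, and 1172 and 973 of these differed at least 2-fold. The median absolute log2 fold change of the genes that passed was 0.66. The ratio was tested against 0, which leaves out the spread of the mock culture itself, here and in each comparison with mock below. With 1 ATRA array left, the count was 4760 without TERA2_ATRA replicate 1 and 4855 without TERA2_ATRA replicate 2.

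What did the azacytidine drug do in TERA2? The p53 targets rose. So did 25 of 67 cancer-testis genes, which are normally expressed in germ cells. Of pluripotency genes 21 of 36 fell, but those list calls ended with an estimated correlation. VCX2 rose 25.3-fold (log2 4.66 ± 0.12, n = 2, adjusted p = 9.17e-06) and its near-identical family member VCX rose 24.4-fold (log2 4.61 ± 0.16, adjusted p = 9.17e-06, 2 other probes 1.79 to 4.60). XAGE1 (log2 4.42 ± 0.24), PAGE5 (log2 4.38 ± 0.11, 1 other probe 2.48) and PAGE2 (log2 3.96 ± 0.09) rose too; in these families a probe may read more than 1 member, so the single genes are uncertain. Outside that group, the calcium-binding S100A6 (log2 4.28 ± 0.41), the membrane protein EMP1 (log2 4.18 ± 0.05, 1 other probe 1.77) and the small GTPase RRAD (log2 3.76 ± 0.06) were among the largest rises.

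The largest falls after Aza were DNMT3B, 11.7-fold (log2 -3.55 ± 0.18, adjusted p = 6.52e-05), and the pluripotency factor SOX2, 11.3-fold (log2 -3.50 ± 0.05, adjusted p = 4.52e-05). CRIPTO (log2 -3.32 ± 0.06), its near-identical copy TDGF3 (log2 -2.67 ± 0.11, uncertain for that reason), and GDF3, a growth factor of pluripotent cells (log2 -2.94 ± 0.11), fell. So did the dicarboxylate transporter SLC13A3 (log2 -2.98 ± 0.24), VAT1L (log2 -2.89 ± 0.13) and the CD30 receptor gene TNFRSF8 (log2 -2.75 ± 0.20). Among the 11 followed genes, TIMP3 (log2 1.75 ± 0.07, 1 other probe 0.07), CDKN1A (log2 1.33 ± 0.03), CDKN2A (log2 0.96 ± 0.05) and GATA4 (log2 0.71 ± 0.09, 1 other probe -0.07) rose. CYP26A1 (log2 -2.11 ± 0.05) and NANOG (log2 -1.41 ± 0.08) fell, and POU5F1 fell at least 2.65-fold with a saturated mock signal (log2 -1.41 ± 0.49). SFRP1 fell (log2 -0.59 ± 0.06), with an adjusted p of 0.0729 without TERA2_Aza replicate 1 and 0.101 without TERA2_Aza replicate 2. EZH2 fell (log2 -0.41 ± 0.05), with an adjusted p of 0.109 without TERA2_Aza replicate 1, 0.159 without TERA2_Aza replicate 2 and 0.155 for the mean of its probes. SOX17 (log2 0.02) did not pass.

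Among p53 targets after Aza, 30 of 35 rose, 0 fell and 5 did not pass (31 and 0 adjusted over the list alone). These p53 targets had a median of log2 1.07 (adjusted p = 2.22e-21, and adjusted p = 0.0465 with an estimated correlation), for example GDF15 (log2 3.74), SFN (log2 2.34) and TP53I3 (log2 2.29). Among mesenchyme and matrix genes, 28 of 39 rose, 0 fell and 11 did not pass (29 and 0 adjusted over the list alone). Mesenchyme genes had a median of log2 0.82 (adjusted p = 8.78e-14, and adjusted p = 0.0465 with an estimated correlation), with the matricellular CCN2 at log2 3.50 and collagen COL1A2 at log2 2.94. Among cancer-testis genes, 25 of 67 rose, 1 fell and 41 did not pass (26 and 1 adjusted over the list alone). Cancer-testis genes had a median of log2 0.25 (adjusted p = 1.06e-08, and adjusted p = 0.0976 with an estimated correlation), among them GAGE7 (log2 2.99, an uncertain paralog). G2/M genes fell: 29 of 34 fell, 0 rose and 5 did not pass (31 and 0 adjusted over the list alone). G2/M genes had a median of log2 -0.79 (adjusted p = 4.42e-19, and adjusted p = 0.0719 with an estimated correlation), including BUB1 (log2 -1.32) and PLK1 (log2 -1.24). In the G1/S list, 23 of 33 fell, 1 rose and 9 did not pass (24 and 1 adjusted over the list alone). G1/S genes had a median of log2 -0.60 (adjusted p = 1.72e-12, and adjusted p = 0.0465 with an estimated correlation), including the replication helicase gene MCM6 (log2 -1.42). Among replication-dependent histones, 20 of 28 fell, 0 rose and 8 did not pass (24 and 0 adjusted over the list alone). Histone genes had a median of log2 -0.80 (adjusted p = 2.7e-16, and adjusted p = 0.0465 with an estimated correlation), for example H4C6 (log2 -2.66). Among pluripotency genes, 21 of 36 fell, 5 rose and 10 did not pass (21 and 5 adjusted over the list alone). Pluripotency genes had a median of log2 -0.77 (adjusted p = 2.92e-07, and adjusted p = 0.227 with an estimated correlation).

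Further lists that rose after Aza were HLA and presentation genes, where 9 of 18 rose, 0 fell and 9 did not pass (10 and 0 adjusted over the list alone). HLA and presentation genes had a median of log2 0.44 (adjusted p = 6.22e-05, and adjusted p = 0.0719 with an estimated correlation), with TAP1 at log2 2.82. Among genes known to be induced by histone deacetylase inhibitors, 19 of 31 rose, 6 fell and 6 did not pass (20 and 6 adjusted over the list alone). Inhibitor-induced genes had a median of log2 0.82 (adjusted p = 1.37e-04, and adjusted p = 0.316 with an estimated correlation), including the neurofilament genes NEFL (log2 2.89) and NEFM (log2 2.16). Among metallothioneins, metal-binding proteins with near-identical members, 7 of 12 rose, 1 fell and 4 did not pass (7 and 1 adjusted over the list alone). Metallothioneins had a median of log2 0.69 (adjusted p = 0.00114, and adjusted p = 0.400 with an estimated correlation), for example MT2A (log2 1.15). Among tumour-hypermethylated genes, 29 of 75 rose, 8 fell and 38 did not pass (31 and 9 adjusted over the list alone). Tumour-hypermethylated genes had a median of log2 0.20 (adjusted p = 0.00140, and adjusted p = 0.0726 with an estimated correlation). EFEMP1 (log2 2.34) and CDKN2B (log2 2.09) rose and the chemokine CXCL12 fell (log2 -2.05).

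Of 29851 genes tested for Aza, 6996 passed (4030 higher, 2966 lower). The median absolute log2 fold change of those that passed was 0.59, and 945 rose and 402 fell at least 2-fold. With 1 Aza array left, 2641 genes passed without TERA2_Aza replicate 1 and 2905 without TERA2_Aza replicate 2.

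What did TSA do in TERA2? Among metallothioneins 10 of 12 rose and among pluripotency genes 21 of 36 fell, but no list call was kept with an estimated correlation. The matricellular protein gene CCN2 rose 22.9-fold (log2 4.51 ± 0.65, n = 2, adjusted p = 1.73e-04) and the neurofilament NEFM rose 22.7-fold (log2 4.51 ± 0.20, adjusted p = 5.66e-05). ARRDC4, an arrestin family member, rose at least 13.2-fold, a lower bound because its mock signal was not well above background (log2 3.83 ± 0.89). The polyamine enzyme SAT1 (log2 3.53 ± 0.37), the cell cycle inhibitor CDKN2D (log2 3.37 ± 0.20) and the inflammasome gene NALP1 (log2 3.20 ± 0.67) rose. DHRS2, a short-chain dehydrogenase (log2 3.19 ± 0.75, 1 other probe 3.90), and CGREF1 (log2 3.13 ± 0.47) rose as well.

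The deepest fall after TSA was that of CRIPTO, 11.9-fold (log2 -3.58 ± 0.62, adjusted p = 1.86e-04), followed by the gap junction gene GJA1 (log2 -3.40 ± 0.32, 1 other probe -1.04) and the activin antagonist FST (log2 -3.26 ± 0.56). NREP (log2 -3.20 ± 0.03), GDF3 (log2 -3.20 ± 0.88), the RNA-binding IGF2BP1 (log2 -3.19 ± 0.54), the glutamine transporter SLC38A1 (log2 -3.06 ± 0.30) and the aminotransferase BCAT1 (log2 -2.95 ± 0.16) fell too. Among the followed genes, TIMP3 (log2 1.46 ± 0.56, 1 other probe -0.03) and SFRP1 (log2 1.21 ± 0.25) rose, and NANOG (log2 -2.40 ± 0.20), CYP26A1 (log2 -2.29 ± 0.78) and DNMT3B (log2 -1.35 ± 0.21) fell. POU5F1 fell (log2 -0.91 ± 0.08), with an adjusted p of 0.138 without TERA2_TSA replicate 1 and 0.0639 without TERA2_TSA replicate 2. CDKN1A fell (log2 -0.44 ± 0.16), with an adjusted p of 0.120 without TERA2_TSA replicate 1. SOX17 (log2 0.00), GATA4 (log2 -0.08) and CDKN2A (log2 -0.09) did not pass, nor did EZH2 (log2 -0.25), whose adjusted p was 0.0119 with a replicate block.

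Metallothioneins rose after TSA: 10 of 12 rose, 0 fell and 2 did not pass (10 and 0 adjusted over the list alone). Metallothioneins had a median of log2 2.50 (adjusted p = 5.43e-11, and adjusted p = 0.345 with an estimated correlation), with MT1G at log2 2.74 and MT2A at log2 2.70, though near-identical members cannot be told apart with certainty. Among genes known to be induced by deacetylase inhibitors, 18 of 31 rose, 2 fell and 11 did not pass (19 and 2 adjusted over the list alone). Inhibitor-induced genes had a median of log2 0.59 (adjusted p = 2.71e-07, and adjusted p = 0.345 with an estimated correlation), including clusterin CLU (log2 2.82), the thioredoxin inhibitor TXNIP (log2 2.63) and the linker histone H1-2 (log2 2.31). Pluripotency genes fell: 21 of 36 fell, 3 rose and 12 did not pass (21 and 3 adjusted over the list alone). Pluripotency genes had a median of log2 -0.66 (adjusted p = 3.97e-07, and adjusted p = 0.345 with an estimated correlation), among them SOX2 (log2 -2.73). In the G2/M list, 22 of 34 fell, 2 rose and 10 did not pass (24 and 3 adjusted over the list alone). G2/M genes had a median of log2 -0.46 (adjusted p = 3.97e-07, and adjusted p = 0.345 with an estimated correlation). The transcription factor FOXM1 (log2 -1.25) fell and the kinase NEK2 rose (log2 1.30). Among Polycomb and DNA methylation genes, 11 of 37 fell, 1 rose and 25 did not pass (13 and 1 adjusted over the list alone). Polycomb genes had a median of log2 -0.16 (adjusted p = 0.0111, and adjusted p = 0.345 with an estimated correlation), for example PHC1 (log2 -1.47). Among HLA and presentation genes, 7 of 18 rose, 1 fell and 10 did not pass (7 and 1 adjusted over the list alone). HLA and presentation genes had a median of log2 0.10 (adjusted p = 0.0235, and adjusted p = 0.345 with an estimated correlation). Of retinoid targets, 8 of 27 fell, 3 rose and 16 did not pass (9 and 3 adjusted over the list alone). Retinoid targets had a median of log2 -0.13 (adjusted p = 0.0383, and adjusted p = 0.345 with an estimated correlation). In the neural list, 8 of 37 rose, 5 fell and 24 did not pass (9 and 5 adjusted over the list alone). Neural genes had a median of log2 0.10 (adjusted p = 0.0482, and adjusted p = 0.621 with an estimated correlation), among them NEFH (log2 2.01) and INA (log2 1.70). These last 4 calls ended when members shared with other lists were left out, with adjusted p = 0.0551, 0.0522, 0.0510 and 0.209 in that order. The HLA call also ended without TERA2_TSA replicate 2 (adjusted p = 0.0550) and the neural call without TERA2_TSA replicate 1 (adjusted p = 0.273).

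For TSA, 7983 of 29851 genes passed (4163 higher and 3820 lower, 890 and 797 at least 2-fold, median absolute log2 0.62).

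Which genes responded differently to Aza and TSA in TERA2? The phospholipid-binding ANXA1 was higher after Aza by log2 4.80 ± 0.26 (SE; log2 1.86 after Aza and -2.94 after TSA, n = 2 each, adjusted p = 3.51e-04). Among cancer-testis genes, VCX2 was higher after Aza by log2 4.67 ± 0.11, VCX by log2 4.64 ± 0.12 and XAGE1 by log2 4.45 ± 0.14 (adjusted p = 9.92e-05). The immediate early gene EGR1 was lower after Aza, with a difference of log2 -3.40 ± 0.12 (log2 -2.15 after Aza and 1.25 after TSA, adjusted p = 1.08e-04). CGREF1 (log2 -3.22 ± 0.24) was lower after Aza too, as was ARRDC4, whose difference has no exact size because its mock signal was not well above background. The scanner software's own log ratios gave differences of log2 5.41 for XAGE1, -4.27 for CGREF1 and -4.14 for EGR1, and the mean of its probes gave 3.72 for VCX. By list, p53 targets were higher after Aza: 28 of 35 were higher, 0 lower and 7 did not pass (32 and 0 adjusted over the list alone). These p53 targets differed by a median of log2 1.26 (adjusted p = 2.36e-24, and adjusted p = 0.0516 with an estimated correlation). Among mesenchyme genes, 24 of 39 were higher, 0 lower and 15 did not pass (26 and 1 adjusted over the list alone). Mesenchyme genes differed by a median of log2 0.94 (adjusted p = 5.72e-14, and adjusted p = 0.0516 with an estimated correlation). In the cancer-testis list, 23 of 67 were higher, 1 lower and 43 did not pass (24 and 2 adjusted over the list alone). Cancer-testis genes differed by a median of log2 0.25 (adjusted p = 3.91e-07, and adjusted p = 0.169 with an estimated correlation). Of retinoid targets, 10 of 27 were higher, 1 lower and 16 did not pass (11 and 1 adjusted over the list alone). Retinoid targets differed by a median of log2 0.41 (adjusted p = 1.44e-04, and adjusted p = 0.105 with an estimated correlation). Lower after Aza were histone genes, where 21 of 28 were lower, 0 higher and 7 did not pass (25 and 0 adjusted over the list alone). Histone genes differed by a median of log2 -0.91 (adjusted p = 2.49e-16, and adjusted p = 0.0516 with an estimated correlation). Of metallothioneins, 10 of 12 were lower, 0 higher and 2 did not pass (10 and 0 adjusted over the list alone). Metallothioneins differed by a median of log2 -1.75 (adjusted p = 6.48e-11, and adjusted p = 0.2995 with an estimated correlation).

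Cell cycle lists also differed between Aza and TSA in TERA2: among G1/S genes 16 of 33 were lower, 1 higher and 16 did not pass (17 and 2 adjusted over the list alone). G1/S genes differed by a median of log2 -0.44 (adjusted p = 2.35e-06, and adjusted p = 0.105 with an estimated correlation). In the G2/M list, 10 of 34 were lower, 1 higher and 23 did not pass (12 and 1 adjusted over the list alone). G2/M genes differed by a median of log2 -0.26 (adjusted p = 5.64e-05, and adjusted p = 0.2995 with an estimated correlation). Among neural genes, 7 of 37 were lower, 2 higher and 28 did not pass (7 and 2 adjusted over the list alone). Neural genes differed by a median of log2 -0.13 (adjusted p = 0.0273, and adjusted p = 0.466 with an estimated correlation), a call that ended without TERA2_TSA replicate 1 (adjusted p = 0.159) and without TERA2_Aza replicate 2 (adjusted p = 0.0531). Pluripotency genes did not pass between the drugs (5 higher, 6 lower and 25 not passing of 36). In all, 5173 of 29851 genes differed between Aza and TSA, 2856 higher and 2317 lower after Aza. The exposure differed (72 h for Aza, 18 h for TSA), and the count was 2437 without TERA2_Aza replicate 1, 2645 without TERA2_Aza replicate 2 and 3253 without TERA2_TSA replicate 1.

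What did the azacytidine drug do in HCT116? In the cancer-testis list 55 of 70 genes rose, a call that ended with an estimated correlation. The amino acid synthesis genes PHGDH and ASNS were among the deepest falls. UCHL1, a ubiquitin hydrolase, rose 73.0-fold (log2 6.19 ± 0.46, n = 2, adjusted p = 2.79e-04). Among cancer-testis and germ cell genes, XAGE1 (log2 6.10 ± 0.90), PEPP-2 (log2 6.05 ± 0.53), VCX (log2 6.02 ± 0.53, 2 other probes 1.65 to 5.83), CT45A5 (log2 5.94 ± 0.57), PAGE5 (log2 5.87 ± 0.52, 1 other probe 4.41) and GAGE7 (log2 5.82 ± 0.52) rose, all members of families with near-identical copies and so uncertain. The transketolase-like TKTL1 rose by log2 5.87 ± 0.40. The serine synthesis enzyme PHGDH fell 12.1-fold (log2 -3.60 ± 0.38, adjusted p = 3.94e-04), and the stress gene DDIT4 fell 11.9-fold (log2 -3.57 ± 0.62, adjusted p = 5.94e-04). Asparagine synthetase ASNS (log2 -3.49 ± 0.20, 1 other probe 0.43), NIBAN1 (log2 -3.20 ± 0.10), the pseudokinase TRIB3 (log2 -3.18 ± 0.02, 1 other probe -1.36), LURAP1L (log2 -2.80 ± 0.40) and S100A14 (log2 -2.67 ± 0.28) fell too.

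Of the 11 followed genes in HCT116, CYP26A1 (log2 2.35 ± 0.53) and SFRP1 (log2 1.84 ± 0.36) rose after 5Aza, and DNMT3B (log2 -0.92 ± 0.15) and CDKN2A (log2 -0.64 ± 0.09) fell. TIMP3 (log2 0.30 ± 0.04, adjusted p = 0.162), GATA4 (log2 0.20 ± 0.20, adjusted p = 0.193), EZH2 (log2 -0.08) and SOX17 (log2 -0.08, 1 other probe 2.12) did not pass. For SOX17, the mean of its probes gave log2 1.02. CDKN1A rose (log2 0.55 ± 0.01), with an adjusted p of 0.0509 without HCT116_5Aza replicate 2. NANOG fell (log2 -0.78 ± 0.41), with an adjusted p of 0.0813 without HCT116_5Aza replicate 2. POU5F1 passed at log2 0.31 ± 0.05 (3 other probes -0.12 to 0.29), but not for the mean of its probes (adjusted p = 0.434), nor at 1 interquartile range (adjusted p = 0.0946), nor without HCT116_5Aza replicate 1 (adjusted p = 0.269).

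In the cancer-testis list after 5Aza, 55 of 70 rose, 2 fell and 13 did not pass (56 and 3 adjusted over the list alone). Cancer-testis genes lay at a median of log2 1.57 (adjusted p = 5.16e-16, and adjusted p = 0.431 with an estimated correlation). Among genes induced by deacetylase inhibitors, 25 of 31 rose, 3 fell and 3 did not pass (25 and 3 adjusted over the list alone). Inhibitor-induced genes lay at a median of log2 0.88 (adjusted p = 3.86e-07, and adjusted p = 0.431 with an estimated correlation), for example TXNIP (log2 4.04) and H1-2 (log2 3.26). G2/M genes fell: 28 of 34 fell, 1 rose and 5 did not pass (32 and 1 adjusted over the list alone). G2/M genes lay at a median of log2 -0.63 (adjusted p = 3.45e-12, and adjusted p = 0.431 with an estimated correlation), including HMMR (log2 -1.53) and CCNB2 (log2 -1.35). Among ribosomal protein genes, 25 of 57 fell, 0 rose and 32 did not pass (27 and 0 adjusted over the list alone). Ribosomal protein genes lay at a median of log2 -0.34 (adjusted p = 4.47e-07, and adjusted p = 0.559 with an estimated correlation), with RPL22 at log2 -1.58 and RPL3 at log2 -1.52. Among metallothioneins, 9 of 12 fell, 0 rose and 3 did not pass (10 and 0 adjusted over the list alone). Metallothioneins lay at a median of log2 -0.81 (adjusted p = 3.36e-04, and adjusted p = 0.431 with an estimated correlation), for example MT1X (log2 -0.91, an uncertain paralog). Among mesenchyme genes, 19 of 39 rose, 2 fell and 18 did not pass (19 and 5 adjusted over the list alone). Mesenchyme genes lay at a median of log2 0.22 (adjusted p = 0.00212, and adjusted p = 0.431 with an estimated correlation), with CCN2 at log2 4.13. Among p53 targets, 20 of 35 rose, 7 fell and 8 did not pass (21 and 7 adjusted over the list alone). These p53 targets lay at a median of log2 0.46 (adjusted p = 0.0127, and adjusted p = 0.431 with an estimated correlation), including PLK2 (log2 2.80) and the death receptor FAS (log2 2.68). Among replication-dependent histones, 14 of 28 rose, 4 fell and 10 did not pass (14 and 4 adjusted over the list alone). Histone genes lay at a median of log2 0.53 (adjusted p = 0.0236, and adjusted p = 0.431 with an estimated correlation), for example H2AC8 (log2 3.76).

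Among tumour-hypermethylated genes after 5Aza in HCT116, 27 of 76 rose, 11 fell and 38 did not pass (28 and 11 adjusted over the list alone). Tumour-hypermethylated genes lay at a median of log2 0.16 (adjusted p = 0.0358, and adjusted p = 0.431 with an estimated correlation). The protease inhibitor TFPI2 (log2 5.30, 1 other probe 0.91), vimentin VIM (log2 4.07) and the matrix protein SPARC (log2 3.59) rose. Among G1/S genes, 15 of 33 fell, 7 rose and 11 did not pass (15 and 7 adjusted over the list alone). G1/S genes lay at a median of log2 -0.15 (adjusted p = 0.0236, and adjusted p = 0.559 with an estimated correlation). CDT1 fell (log2 -1.24) and the replication clamp PCNA rose (log2 1.53). That G1/S call ended without HCT116_5Aza replicate 2 (adjusted p = 0.0578). Among endoderm and trophoblast genes, 8 of 27 rose, 1 fell and 18 did not pass (8 and 1 adjusted over the list alone). Endoderm and trophoblast genes lay at a median of log2 0.20 (adjusted p = 0.0358, and adjusted p = 0.431 with an estimated correlation), with CXCR4 at log2 2.15, a call that ended without HCT116_5Aza replicate 1 (adjusted p = 0.140). Among interferon response genes, 22 of 48 rose, 8 fell and 18 did not pass (23 and 9 adjusted over the list alone). Interferon response genes lay at a median of log2 0.24 (adjusted p = 0.0358, and adjusted p = 0.431 with an estimated correlation), including IFI27 (log2 3.92) and MX1 (log2 2.04). Their call ended with a replicate block (adjusted p = 0.0546), without HCT116_5Aza replicate 2 (adjusted p = 0.0578), and without HCT116_TSA replicate 1 or 2 (adjusted p = 0.0546 and 0.0546).

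Of 31388 genes in HCT116, 11651 passed after 5Aza, 6612 higher and 5039 lower, with a median absolute log2 of 0.64; 1714 rose and 835 fell at least 2-fold. All HCT116 arrays carried the treated RNA in Cy5, so a gene-specific dye effect stays in these values, and their spot backgrounds were not available. The count was 7695 without HCT116_5Aza replicate 1 and 6845 without HCT116_5Aza replicate 2.

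What did TSA do in HCT116? Of the histone genes 14 of 28 rose, a call that ended with an estimated correlation, and DDIT4 was the deepest fall. The dehydrogenase DHRS2 rose 15.5-fold (log2 3.95 ± 0.50, n = 2, adjusted p = 0.00138, 1 other probe 4.47) and the germ cell gene TEX19 rose 14.3-fold (log2 3.84 ± 0.10, adjusted p = 0.00103). The Wnt antagonist DKK1 (log2 3.79 ± 0.17), the linker histone H1-2 (log2 3.25 ± 0.05), EID3 (log2 3.19 ± 0.12) and the keratin-associated KRTAP3-1 (log2 3.09 ± 0.10) rose, as did the histone genes H2BC4 (log2 2.91 ± 0.24) and H2BC15 (log2 2.78 ± 0.14), which have near-identical copies and are uncertain. DDIT4 fell 9.57-fold (log2 -3.26 ± 0.25, adjusted p = 0.00177). LEMD1 (log2 -3.20 ± 0.44), the gluconeogenic PCK2 (log2 -2.84 ± 0.07), ANGPTL4 (log2 -2.79 ± 0.26) and the receptor subunit IL20RB (log2 -2.66 ± 0.04) fell. Falls were also measured for the stress factor DDIT3 (log2 -2.65 ± 0.19), KRCC1 (log2 -2.60 ± 0.25) and DHRS3 (log2 -2.57 ± 0.33).

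Of the followed genes, DNMT3B (log2 -0.74 ± 0.14), CDKN2A (log2 -0.72 ± 0.06), POU5F1 (log2 -0.77 ± 0.08, 3 other probes -0.15 to 0.24) and CDKN1A (log2 -0.53 ± 0.07) fell after TSA in HCT116, each losing its call without 1 array. The adjusted p was 0.0752 for DNMT3B without HCT116_TSA replicate 1, 0.0574 for CDKN2A and 0.0505 for POU5F1 without HCT116_TSA replicate 2. For CDKN1A it was 0.100 without HCT116_TSA replicate 1 and 0.0697 without HCT116_TSA replicate 2. With the mean of a gene's probes, POU5F1 (adjusted p = 0.147) and CDKN1A (adjusted p = 0.110) did not pass. CYP26A1 (log2 0.26), EZH2 (log2 0.24), TIMP3 (log2 0.24), SFRP1 (log2 0.20), GATA4 (log2 -0.05), SOX17 (log2 -0.13) and NANOG (log2 -0.52) did not pass. NANOG did with a replicate block (adjusted p = 0.0161).

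Replication-dependent histones rose after TSA in HCT116: 14 of 28 rose, 0 fell and 14 did not pass (15 and 0 adjusted over the list alone). Histone genes lay at a median of log2 0.38 (adjusted p = 8.07e-06, and adjusted p = 0.729 with an estimated correlation), including H2BC9 (log2 2.66) and H2BC14 (log2 2.55). Among deacetylase inhibitor-induced genes, 13 of 31 rose, 4 fell and 14 did not pass (17 and 4 adjusted over the list alone). Inhibitor-induced genes lay at a median of log2 0.29 (adjusted p = 0.00230, and adjusted p = 0.729 with an estimated correlation), for example H2BC12 (log2 2.70). Among G1/S genes, 17 of 33 rose, 6 fell and 10 did not pass (21 and 7 adjusted over the list alone). G1/S genes lay at a median of log2 0.37 (adjusted p = 0.00351, and adjusted p = 0.729 with an estimated correlation), with the cyclin CCNE2 at log2 1.07 and CDC6 at log2 0.90. In the G2/M list, 9 of 34 fell, 2 rose and 23 did not pass (10 and 2 adjusted over the list alone). G2/M genes lay at a median of log2 -0.14 (adjusted p = 0.0116, and adjusted p = 0.729 with an estimated correlation), for example CKS1B (log2 -0.99). Among ribosomal protein genes, 20 of 57 fell, 0 rose and 37 did not pass (20 and 0 adjusted over the list alone). Ribosomal protein genes lay at a median of log2 -0.29 (adjusted p = 4.12e-05, and adjusted p = 0.729 with an estimated correlation), a call that ended without HCT116_TSA replicate 1 (adjusted p = 0.0909). Its largest member RPL3 (log2 -0.77) had an adjusted p of 0.0764 without HCT116_TSA replicate 1 and 0.0568 without HCT116_TSA replicate 2. Among metallothioneins, 5 of 12 rose, 0 fell and 7 did not pass (5 and 0 adjusted over the list alone). Metallothioneins lay at a median of log2 0.35 (adjusted p = 0.0130, and adjusted p = 0.729 with an estimated correlation), among them MT1G (log2 0.94), and their call ended without HCT116_TSA replicate 2 (adjusted p = 0.148).

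For TSA in HCT116, 8260 of 31388 genes passed (4377 higher, 3883 lower; 700 and 533 at least 2-fold; median absolute log2 0.60). The mock was kept in PBS for 96 h while TSA lasted 18 h, and the count was 2665 without HCT116_TSA replicate 1 and 2540 without HCT116_TSA replicate 2.

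Which genes differed between 5Aza and TSA in HCT116? The cancer-testis gene VCX was higher after 5Aza by log2 5.97 ± 0.27 (SE; log2 6.02 after 5Aza and 0.06 after TSA, n = 2 each, adjusted p = 0.00338). The ubiquitin hydrolase UCHL1 (log2 5.83 ± 0.24) and the germ cell genes XAGE1 (log2 5.61 ± 0.47) and PEPP-2 (log2 5.52 ± 0.26) were higher too. Lower after 5Aza were the muscle gene MYOM2 (log2 -3.10 ± 0.41, adjusted p = 0.0127), the receptor KLRC2 (log2 -3.05 ± 0.28), lamin LMNB1 (log2 -2.75 ± 0.13) and the transporter ABCC2 (log2 -2.48 ± 0.15). With all arrays at the same interquartile range, these differences were log2 4.14 for VCX, 4.005 for UCHL1, 3.83 for XAGE1, 3.78 for PEPP-2, -1.93 for LMNB1, -2.18 for KLRC2 and -2.48 for MYOM2, and the mean of its probes gave 4.43 for VCX. XAGE1 differed by log2 6.25 without HCT116_5Aza replicate 1 and 4.97 without HCT116_5Aza replicate 2. MYOM2 differed by log2 -3.70 without HCT116_TSA replicate 1 and -2.51 without HCT116_TSA replicate 2. In the cancer-testis list, 47 of 70 were higher, 2 lower and 21 did not pass (53 and 2 adjusted over the list alone). Cancer-testis genes differed by a median of log2 1.37 (adjusted p = 1.38e-22, and adjusted p = 0.304 with an estimated correlation). Of p53 targets, 15 of 35 were higher, 0 lower and 20 did not pass (18 and 1 adjusted over the list alone). These p53 targets differed by a median of log2 0.45 (adjusted p = 3.04e-06, and adjusted p = 0.304 with an estimated correlation). Of interferon genes, 17 of 48 were higher, 1 lower and 30 did not pass (18 and 3 adjusted over the list alone). Interferon response genes differed by a median of log2 0.28 (adjusted p = 2.04e-05, and adjusted p = 0.304 with an estimated correlation). Of mesenchyme genes, 10 of 39 were higher, 0 lower and 29 did not pass (11 and 0 adjusted over the list alone). Mesenchyme genes differed by a median of log2 0.25 (adjusted p = 5.67e-05, and adjusted p = 0.304 with an estimated correlation). Among tumour-hypermethylated genes, 17 of 76 were higher, 3 lower and 56 did not pass (20 and 4 adjusted over the list alone). Tumour-hypermethylated genes differed by a median of log2 0.15 (adjusted p = 6.02e-04, and adjusted p = 0.304 with an estimated correlation). Of pluripotency genes, 8 of 36 were higher, 1 lower and 27 did not pass (11 and 2 adjusted over the list alone). Pluripotency genes differed by a median of log2 0.07 (adjusted p = 0.0109, and adjusted p = 0.304 with an estimated correlation). Among G2/M genes, 12 of 34 were lower, 1 higher and 21 did not pass (19 and 2 adjusted over the list alone). G2/M genes differed by a median of log2 -0.49 (adjusted p = 2.4e-09, and adjusted p = 0.304 with an estimated correlation). Among G1/S genes, 13 of 33 were lower, 0 higher and 20 did not pass (19 and 1 adjusted over the list alone). G1/S genes differed by a median of log2 -0.45 (adjusted p = 1.22e-07, and adjusted p = 0.304 with an estimated correlation). Among metallothioneins, 8 of 12 were lower, 0 higher and 4 did not pass (9 and 0 adjusted over the list alone). Metallothioneins differed by a median of log2 -1.10 (adjusted p = 6.68e-07, and adjusted p = 0.304 with an estimated correlation). The test passed 3974 of 31388 genes, 2449 higher and 1525 lower after 5Aza. Leaving out arrays gave 2367 (without HCT116_5Aza replicate 1), 1704 (without HCT116_5Aza replicate 2), 733 (without HCT116_TSA replicate 1) and 573 (without HCT116_TSA replicate 2).

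**Figure D1:**
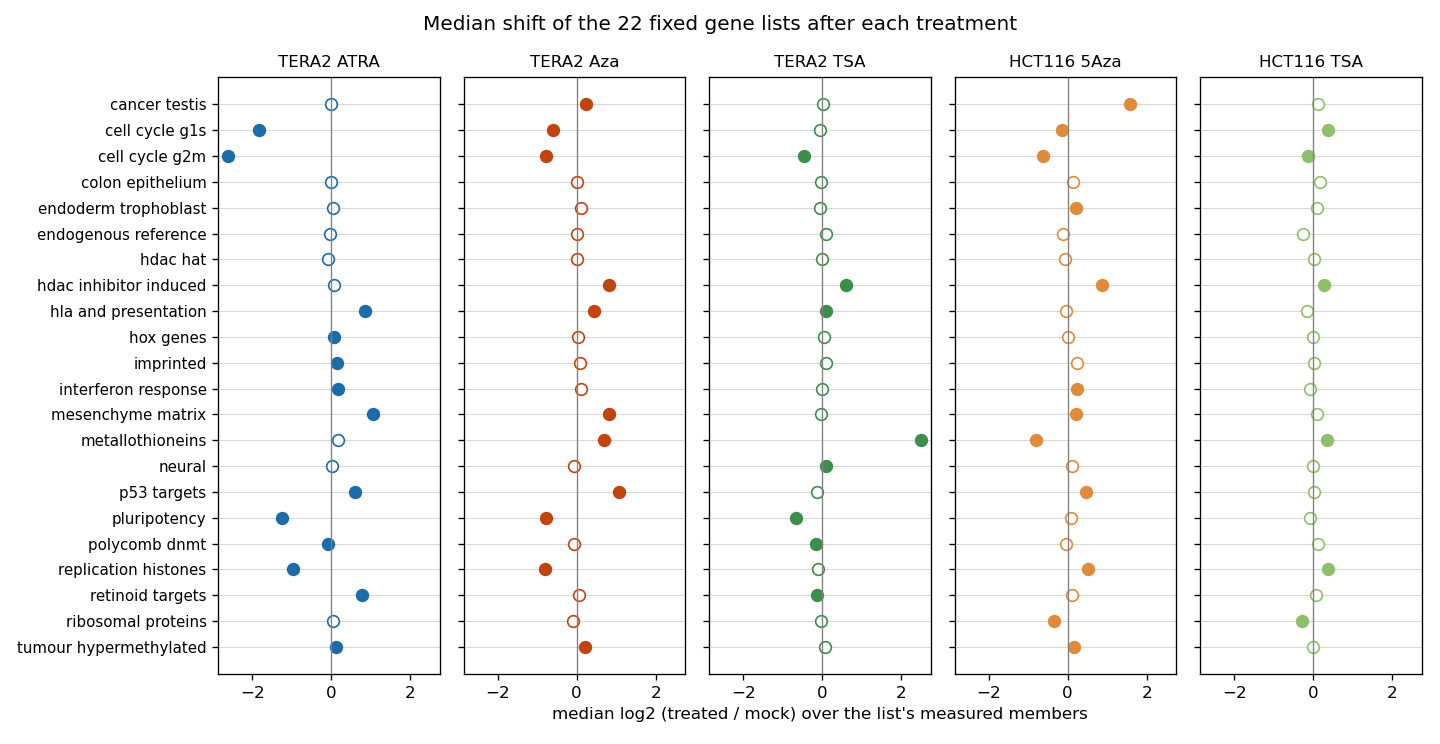
Each of the 5 panels is 1 treatment, with 22 gene lists on the y axis and the median log2 of treated over mock of a list's measured members on the x axis; filled points passed the limma camera test at an adjusted p under 0.05 and open points did not. Cancer-testis genes lay at 1.57 after 5Aza in HCT116 and at 0.25 after Aza in TERA2.

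How did the response to each drug differ between HCT116 and TERA2? For the azacytidine drug, the RNA-binding L1TD1 was higher in HCT116 by log2 5.78 ± 0.16 (SE; log2 4.23 in HCT116 and -1.55 in TERA2, n = 2 each, adjusted p = 2.01e-07). The cancer-testis helicase DDX43 (log2 5.75 ± 0.67), CT45A5 (log2 5.65 ± 0.21) and TKTL1 (log2 5.53 ± 0.20) were higher in HCT116 too. The DDX43 difference was log2 4.52 without TERA2_Aza replicate 1 and 6.98 without TERA2_Aza replicate 2. EMP1 was lower in HCT116, with a difference of log2 -5.21 ± 0.16 (log2 -0.82 against 4.39, adjusted p = 2.01e-07), as were GDF15 (log2 -4.84 ± 0.28), S100A6 (log2 -4.32 ± 0.31) and IL20RB (log2 -4.29 ± 0.16). With all arrays at the same interquartile range, the differences were log2 4.94 for L1TD1, 4.65 for DDX43, 3.76 for CT45A5, 3.64 for TKTL1, -5.55 for S100A6, -5.74 for GDF15 and -6.23 for EMP1, and the mean of its probes gave -3.91 for EMP1. By list, histone genes were higher in HCT116: 23 of 28 were higher, 1 lower and 4 did not pass (23 and 1 adjusted over the list alone). Histone genes stood apart by a median of log2 1.89 (adjusted p = 3.06e-13, and adjusted p = 0.0928 with an estimated correlation). Among cancer-testis genes, 49 of 70 were higher, 4 lower and 17 did not pass (52 and 4 adjusted over the list alone). Cancer-testis genes stood apart by a median of log2 1.16 (adjusted p = 5.23e-13, and adjusted p = 0.225 with an estimated correlation). With all arrays at the same interquartile range that median was 0.45, with 32 higher, 9 lower and 29 not passing. Among pluripotency genes, 22 of 36 were higher, 1 lower and 13 did not pass (23 and 3 adjusted over the list alone). Pluripotency genes stood apart by a median of log2 1.12 (adjusted p = 1.87e-07, and adjusted p = 0.0928 with an estimated correlation). Among G1/S genes, 16 of 33 were higher, 3 lower and 14 did not pass (18 and 3 adjusted over the list alone). G1/S genes stood apart by a median of log2 0.35 (adjusted p = 0.00297, and adjusted p = 0.418 with an estimated correlation). Metallothioneins were lower in HCT116: 9 of 12 were lower, 1 higher and 2 did not pass (9 and 1 adjusted over the list alone). Metallothioneins stood apart by a median of log2 -1.57 (adjusted p = 1.33e-05, and adjusted p = 0.232 with an estimated correlation). Among p53 targets, 21 of 35 were lower, 8 higher and 6 did not pass (21 and 8 adjusted over the list alone). These p53 targets stood apart by a median of log2 -0.77 (adjusted p = 1.53e-05, and adjusted p = 0.323 with an estimated correlation). Among ribosomal protein genes, 14 of 57 were lower, 0 higher and 43 did not pass (12 and 0 adjusted over the list alone). Ribosomal protein genes stood apart by a median of log2 -0.34 (adjusted p = 0.00105, and adjusted p = 0.565 with an estimated correlation). Among HLA and presentation genes, 9 of 19 were lower, 1 higher and 9 did not pass (9 and 1 adjusted over the list alone). HLA and presentation genes stood apart by a median of log2 -0.45 (adjusted p = 0.00297, and adjusted p = 0.225 with an estimated correlation). Among mesenchyme genes, 15 of 39 were lower, 5 higher and 19 did not pass (15 and 5 adjusted over the list alone). Mesenchyme genes stood apart by a median of log2 -0.18 (adjusted p = 0.00659, and adjusted p = 0.377 with an estimated correlation).

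For TSA, the gap junction gene GJA1 was higher in HCT116 by log2 4.18 ± 0.15 (log2 0.62 in HCT116 and -3.56 in TERA2, adjusted p = 1.72e-06), followed by DKK1 (log2 3.68 ± 0.17), the chaperone cofactor BAG2 (log2 3.66 ± 0.14) and NREP (log2 3.63 ± 0.25). NALP1 was lower in HCT116, with a difference of log2 -4.80 ± 0.15 (log2 -1.50 against 3.30, adjusted p = 1.36e-06), as were NEFM (log2 -4.63 ± 0.28), the kinase MKNK2 (log2 -3.94 ± 0.21) and, without an exact size, ARRDC4. At the same interquartile range the differences were log2 5.09 for GJA1, 2.98 for DKK1, 4.58 for NREP, -6.09 for NEFM and -5.47 for NALP1, and with the mean of a gene's probes 2.25 for GJA1, 2.69 for NREP and -2.53 for MKNK2. Metallothioneins were lower in HCT116: 10 of 12 were lower, 0 higher and 2 did not pass (10 and 0 adjusted over the list alone). Metallothioneins stood apart by a median of log2 -2.02 (adjusted p = 1.16e-09, and adjusted p = 0.171 with an estimated correlation). Among histone genes, 20 of 28 were higher, 2 lower and 6 did not pass (21 and 2 adjusted over the list alone). Histone genes stood apart by a median of log2 1.105 (adjusted p = 4.79e-08, and adjusted p = 0.171 with an estimated correlation). Of G1/S genes, 18 of 33 were higher, 4 lower and 11 did not pass (20 and 4 adjusted over the list alone). G1/S genes stood apart by a median of log2 0.53 (adjusted p = 3.27e-04, and adjusted p = 0.372 with an estimated correlation). Of pluripotency genes, 16 of 36 were higher, 3 lower and 17 did not pass (16 and 3 adjusted over the list alone). Pluripotency genes stood apart by a median of log2 0.28 (adjusted p = 3.27e-04, and adjusted p = 0.171 with an estimated correlation). Among Polycomb and DNA methylation genes, 16 of 37 were higher, 2 lower and 19 did not pass (17 and 4 adjusted over the list alone). Polycomb genes stood apart by a median of log2 0.29 (adjusted p = 0.0397, and adjusted p = 0.171 with an estimated correlation), a call that ended without shared members (adjusted p = 0.149). It also ended without HCT116_TSA replicate 1 (adjusted p = 0.0602) or 2 (adjusted p = 0.0503), HCT116_5Aza replicate 1 or 2 (both adjusted p = 0.0528) and TERA2_TSA replicate 1 (adjusted p = 0.0677). Among ribosomal protein genes, 9 of 57 were lower, 3 higher and 45 did not pass (9 and 2 adjusted over the list alone). Ribosomal protein genes stood apart by a median of log2 -0.30 (adjusted p = 0.0397, and adjusted p = 0.581 with an estimated correlation). This call ended without HCT116_TSA replicate 1 (adjusted p = 0.415) and without TERA2_TSA replicate 2 (adjusted p = 0.0898).

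Between the lines, 10538 of 31388 genes differed in the response to the azacytidine drug (5646 higher and 4892 lower in HCT116) and 9728 in the response to TSA (4885 higher, 4843 lower). The HCT116 and TERA2 columns of the authors' table appear to have been normalised separately, with interquartile ranges of 0.461 to 0.608 and about 0.31, and the azacytidine exposure was 96 h in HCT116 and 72 h in TERA2. A different analog in each line would enter these values too.

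Did treatments move the same genes? Across genes, which are not independent replicates, 6 correlations of log2 fold changes were computed. In TERA2, ATRA and Aza gave r = 0.643 (Spearman 0.608, covariance 0.161 against a simulated 0.00989). After both, 2346 genes were higher and 2093 lower, against 573 and 386 for independent lists. Pluripotency genes such as NANOG and CRIPTO stood among the shared falls. ATRA and TSA gave r = 0.265 (Spearman 0.244; covariance 0.0701), with 1392 genes higher and 1604 lower after both against 592 and 497. Aza and TSA gave r = 0.353 (Spearman 0.327; covariance 0.0743), with 1487 and 1498 against 562 and 380; DNMT3B, SOX2 and GDF3 fell after both. In HCT116, 5Aza and TSA gave r = 0.562 (Spearman 0.591; covariance 0.1497 against a simulated 0.0120), with 2753 higher and 2519 lower after both against 922 and 623; DDIT4 fell and H1-2 rose after both. A shared mock fixed simulated r (0.5005 in TERA2, 0.499 in HCT116), so only covariances can be compared. Between the lines, the azacytidine drug gave r = 0.252 (Spearman 0.235; covariance 0.0657), with 2191 higher and 1373 lower in both against 1117 and 656, and XAGE1, VCX and PAGE5 rose in both. TSA gave r = 0.115 (Spearman 0.0763; covariance 0.0228), with 1463 and 1155 against 828 and 651, and DHRS2 rose in both. Part of the excess within a line may come from a shared mock, since the labels do not say whether treatments had their own. In HCT116 a dye effect may add to it, as the treated RNA was always in Cy5. Its arrays correlated with the TERA2 dye effect (r = 0.054 to 0.251), and no r without it was computed.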

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

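The tests of the 3 patterns below were chosen only after the results were seen. Each result in the next paragraph is listed because a test of the difference in drug response between the HCT116 and TERA2 cell lines passed.

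For the azacytidine drug, 10538 genes differed between the lines, and for TSA 9728 did. List medians of the HCT116 minus TERA2 difference for the azacytidine drug were log2 1.16 for cancer-testis, 0.35 for G1/S, 1.12 for pluripotency and 1.89 for histone genes. They were -0.45 for HLA and presentation, -0.18 for mesenchyme, -1.57 for metallothionein, -0.77 for p53 target and -0.34 for ribosomal protein genes. For TSA, they were 0.53 for G1/S, 0.28 for pluripotency, 0.29 for Polycomb and DNA methylation, 1.105 for histone, -2.02 for metallothionein and -0.30 for ribosomal protein genes. With an estimated correlation none of these 15 list differences passed (adjusted p = 0.0928 or more), which leaves them undecided. Single genes with the largest differences for the azacytidine drug were L1TD1 (5.78), DDX43 (5.75), CT45A5 (5.65), TKTL1 (5.53), IL20RB (-4.29), S100A6 (-4.32), GDF15 (-4.84) and EMP1 (-5.21). For TSA they were GJA1 (4.18), DKK1 (3.68), BAG2 (3.66), NREP (3.63), MKNK2 (-3.94), ARRDC4 (-4.21, not exact because its TERA2 mock signal was not well above background), NEFM (-4.63) and NALP1 (-4.80).

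Cancer-testis genes rose more in HCT116 than in TERA2, by a median of log2 1.16 over 70 genes, a list call that ended with an estimated correlation (adjusted p = 0.225). The HCT116 columns have a wider scale, and with all arrays at the same interquartile range the median was 0.45 with 32 higher, 9 lower and 29 not passing, so scale could account for part of it. Probes shared between near-identical family members do not account for it, since the median over 38 families was still 0.98 and 30 families lay above 0. The longer exposure of HCT116 could not be told apart from the cell line, since all HCT116 arrays had it and the median there is the same 1.16. Whether both lines received the same analog is not stated.

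Amino acid response genes, of the kind that the transcription factor ATF4 induces, and hypoxia genes were mostly lower after both drugs in HCT116. In lists written after the data were seen, 31 of 38 amino acid response genes fell and 2 rose after 5Aza (median log2 -1.30), and 34 fell and 1 rose after TSA (median log2 -1.18). Among those that fell were DDIT3 (log2 -2.28 and -2.65) and PSAT1 (log2 -1.77 and -1.39). ATF3 rose after both (log2 2.58 and 0.53) and CTH after 5Aza (log2 0.57). Of 30 hypoxia genes 21 fell after each (medians -0.90 and -0.94), and 1 rose after 5Aza. Whether a common mock culture in another nutrient or oxygen state accounts for it could not be told. The median difference between the drugs was log2 -0.0769 (quartiles -0.45 and 0.25, 4 genes lower and 2 higher after 5Aza), but the list was written because both drugs lowered its genes. A median TERA2 dye effect of -0.0262 argues against a dye effect. TERA2 list medians were 0.000696 after Aza (quartiles -0.34 and 0.47, 11 rose, 9 fell) and -0.00238 after TSA (11 rose, 11 fell). This argues against a drug action on the whole list in both lines, but not one in HCT116 alone. For single genes it stays open, since in TERA2 PHGDH (log2 -1.48 after Aza and -0.49 after TSA) and PSAT1 (log2 -0.89 and -0.56) fell after both, while ASNS fell after Aza (log2 -1.02) and rose after TSA (log2 0.73). Whether the mock or the drugs moved these genes stays open, since no array compared mock with untreated cells.

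ATRA and Aza log2 fold changes correlated across genes in TERA2. Whether a shared mock accounts for it could not be told. Chance values of a shared mock RNA would add a simulated covariance of 0.00989 against the observed 0.161, but the simulation holds only the spread between arrays and not the state of a mock culture. A dye effect does not account for it, since arrays of opposite dye orientation gave a mean r of 0.557. A loss of dividing embryonal cells under both treatments could not be told from other causes: r was 0.636 without 131 genes of the pluripotency, cell cycle and histone lists.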

How the results depend on the processing

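Leaving out arrays for the gene lists and correlations, and subtracting the TERA2 dye effect from HCT116 arrays, were alternatives chosen only after the results were seen; the others were planned. A lone array left in a group is assumed to vary like the other groups, and 2 arrays per group and a median red signal of 174 to 255 over 59 to 61 limit what small changes can be called.

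With a replicate block the number of genes past the threshold was 11363 for TERA2 Aza, 12070 for TERA2 TSA and 9386 for Aza minus TSA (from 6996, 7983 and 5173). The block takes up the dye orientation in TERA2, and it moved no other count of genes by over 1.5 times. With all 10 arrays sharing the spread, 5Aza minus TSA in HCT116 gave 6423 (from 3974), and the cause was not tested. Other alternatives that kept all arrays gave 8013 to 12075 genes for ATRA, 9912 to 14186 for 5Aza and 7766 to 11208 for TSA in HCT116, 8193 to 11180 between the lines for the azacytidine drug and 9191 to 10488 for TSA.

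With each array left out in turn, the counts were 4760 to 8650 for ATRA, 2641 to 7498 for TERA2 Aza, 3579 to 7505 for TERA2 TSA and 2437 to 5420 for Aza minus TSA. In HCT116 they were 6845 to 10851 for 5Aza, 2540 to 7901 for TSA and 573 to 2367 for their difference. Between the lines they were 7136 to 10838 for the azacytidine drug and 7378 to 9985 for TSA. These fits hold fewer arrays.

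With an estimated correlation, 5 lists (from 13) passed for ATRA and 4 (from 11) for TERA2 Aza. None passed for TERA2 TSA, Aza minus TSA, the 3 HCT116 comparisons and the 2 between the lines. In limma fry, which asks whether a list moves one way and sets it against no other genes, 15 lists passed for ATRA, 16 for TERA2 Aza, 14 for TERA2 TSA, 15 for Aza minus TSA and 16 for HCT116 5Aza. It passed only 2 for HCT116 TSA, where the G1/S, G2/M, metallothionein and ribosomal calls failed (adjusted p = 0.0587 to 0.162), 11 for 5Aza minus TSA, and 16 and 16 between the lines. The ribosomal calls for 5Aza in HCT116 and for TSA between the lines failed it too (adjusted p = 0.0628 and 0.140). Without members in more than 1 list, 4 lists (from 8) passed for TERA2 TSA. With an array left out, 12 to 13 lists passed for ATRA, 11 to 13 for TERA2 Aza, 7 to 8 for TERA2 TSA, 8 to 10 for Aza minus TSA, 10 to 11 for HCT116 5Aza, 5 to 7 for HCT116 TSA, 9 to 10 for their difference, 9 to 9 between the lines for the azacytidine drug and 5 to 7 for TSA.

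Correlations between single arrays of different replicate numbers were 0.555 and 0.559 for ATRA and Aza, 0.203 and 0.205 for ATRA and TSA, 0.273 and 0.279 for Aza and TSA, and 0.499 and 0.471 for 5Aza and TSA in HCT116; single arrays are noisier than means. For the azacytidine drug in both lines, the correlation was 0.216 to 0.270 with an array left out.

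SOX17 after 5Aza in HCT116 reversed with the mean of its probes (log2 1.02), which stems from a probe at log2 2.12 beside the chosen probe at -0.08. Among 534 results of named genes, 2677 values with an array left out were the same, 153 weaker, 2 stronger, 0 reversed and 5 moved; of other alternatives 4014 were the same, 58 weaker, 5 stronger, 1 reversed and 5 moved. Among 198 list results these numbers were 1169, 19, 16, 0 and 28, and 492, 83, 4, 0 and 15.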

Other observations

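The tests, lists and choice of genes in this part were set before the results were seen. In HCT116, 5Aza raised several genes of pluripotent cells: ZFP42 (log2 4.94 ± 0.50, n = 2), L1TD1 (log2 4.23 ± 0.35), DPPA2 (log2 2.69 ± 0.34) and the let-7 antagonist LIN28B (log2 2.33 ± 0.73) rose. The pluripotency list as a whole did not pass there: 10 rose, 6 fell and 20 did not pass of 36 (10 and 6 adjusted over the list alone), with an adjusted p of 0.560. The neurofilament gene NEFM rose after ATRA (log2 3.56), Aza (log2 2.16) and TSA (log2 4.51) in TERA2 and after 5Aza in HCT116 (log2 1.43), and did not pass after TSA in HCT116 (log2 0.24). No list of neurofilament genes was tested. Among imprinted genes, NAP1L5 rose after TSA in TERA2 (log2 2.09) and after 5Aza (log2 2.04) and TSA (log2 1.87) in HCT116, and PEG10 rose after TSA in both lines (log2 1.40 in TERA2 and 2.53 in HCT116). PHLDA2 (log2 2.54) and MEST (log2 2.35) rose after Aza in TERA2. The imprinted list passed in none of these comparisons in the main test. Of 36 genes, 11 rose and 8 fell after TSA in TERA2 (adjusted p = 0.387) and 10 rose and 6 fell after Aza (adjusted p = 0.0602). In HCT116, 12 rose and 8 fell after 5Aza (adjusted p = 0.219) and 7 rose and 8 fell after TSA (adjusted p = 0.711).

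Within lists that did not pass as a whole after TSA in TERA2, single members moved in opposite directions. Of deacetylase and acetyltransferase genes, 6 rose, 8 fell and 9 did not pass of 23 (6 and 9 adjusted over the list alone), with an adjusted p of 0.883. HDAC1 rose (log2 1.16) and HDAC7 fell (log2 -2.20). In the G1/S list, 5 rose, 10 fell and 18 did not pass of 33 (6 and 11 adjusted over the list alone), with an adjusted p of 0.422. The nucleotide enzyme RRM2 rose (log2 1.46) and thymidylate synthase TYMS fell (log2 -2.59). The endoderm factor GATA6 rose after ATRA (log2 2.71) and Aza (log2 1.09) in TERA2. Its endoderm and trophoblast list passed in neither main test. Of 25 genes, 3 rose and 4 fell after ATRA (adjusted p = 0.855). After Aza 7 rose and 0 fell (adjusted p = 0.0579). There it was 0.0532 with a replicate block, 0.217 with an estimated correlation and 0.0451 without shared members.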
